A study of Mus musculus with 17 samples.

How the data were processed

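Nuclei of newborn hippocampal neurons, labelled by a GFP retrovirus with a synapsin promoter and sorted for GFP and a DNA dye, were sequenced from 17 mice. Per the labels' protocols, cDNA was made with SmartSeq v4 and 18 cycles of PCR, sheared and made into libraries with ThruPLEX, and read from 1 end for 75 nt. No molecular identifiers are named, so amplified copies of a molecule cannot be told from separate molecules, and confidence intervals cover what the libraries show. The labels gave genotype (wild type, or global knockout of Fndc5) and housing (running wheel, or sedentary), which made 4 groups.

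The file the authors deposited holds counts, as whole numbers for 24982 gene symbols in 17 columns, 1 per mouse. Its name calls the counts normalized, while the values had the totals and the scatter of raw reads. Per the submitters' processing notes, STAR 2.5.1b, Cufflinks 2.2.1 and the genome build mm10 were used, with no role or order given, and neither the counting options nor the strand counted are stated. Symbols were in capitals and were joined to GENCODE release M21, which matched 24490 of them (98.03%). Symbols are printed in the usual mouse spelling.

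The design, fixed before the data were examined, named limma on log2 values for normalized values and edgeR with TMM scaling if the file held raw counts. The unit differed from the first assumption, so edgeR 4.0.16 in R 4.3.3 was used (glmQLFit and glmQLFTest, means of the 4 groups, no other term). Genes with a count of at least 10 in at least 4 libraries were kept, 13005 in all. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. The common biological coefficient of variation was 2.59%, with 13 residual and 190 prior degrees of freedom. CPM are counts relative to the library total scaled by TMM, and fold changes are edgeR's.

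7 comparisons were made: running against sedentary in wild-type and in knockout-labelled mice, labelled knockout against wild type in sedentary and in running mice, the difference between genotypes in the running effect, and both effects averaged over the other factor. The genes named were fixed by a rule before the data were examined. For the first 5 comparisons, if 20 or more genes passed, they were the 10 higher and 10 lower with the largest absolute log2 fold change among those past the threshold. Otherwise they were all that passed, filled up to 10 higher and 10 lower with the smallest unadjusted p, stated as not passed. For the 2 averaged comparisons they were the 5 higher and 5 lower with the smallest unadjusted p. From every list described they were 2 to 4 members with the smallest unadjusted p, and Fndc5, Dcx, Prox1, Bdnf, Itgav and Itgb5 were always included. A few genes that these rules name, or that passed in an alternative, are not reported here.

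Before the data were examined 32 gene lists were written, covering cell types of the hippocampus, neuronal functions, metabolism, stress, signalling and chromatin. Of these 29 had at least 5 genes kept and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation and with fry. Of the choroid plexus and ependymal list 4 of 14 genes were kept, so it had no set test. Of the mitochondrial genome list 0 of 15 symbols were in the table, and the sex-linked genes served as a check of the samples. Exact permutation tests and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

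Pairs of libraries were compared by a chi-square index over genes with a summed count of at least 20. The edgeR fit was tested on simulated data with known changes in 50 genes per fold at the depth of these libraries: of 1.5-fold changes 66% were found in the wild-type running comparison, 74% in the sedentary genotype comparison and 58% for the difference in the running effect, with 10, 7 and 4 false calls among 13005 genes.

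Alternatives planned before the data were examined were no filter, a stricter filter, quantile normalization, library quality weights, DESeq2 1.42.0 and the mouse number as a replicate block. Also planned were runs of sample identifiers as a term or the middle run alone, only the groups compared, and each mouse left out in turn. Library totals in place of TMM, limma voom, limma on log2 of CPM plus 1 or 8, and 2 knockout running libraries counted as 1 sample were chosen after seeing the data. The 3 runs of identifiers held 4, 9 and 4 mice. They were grouped in order of number, with gaps between numbers inside a run. The middle run alone held all 4 groups. The first held sedentary mice only, so the term for the runs overlaps in part with housing. No library was left out.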

Results

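The data were RNA sequencing counts from nuclei of newborn hippocampal neurons of 17 mice. A retrovirus with a synapsin promoter, which enters dividing cells and drives GFP in the neurons they become, labelled the cells, and nuclei positive for GFP and a DNA dye were sorted. The series design gives a yield of 200 to 500 nuclei per mouse. The mice were wild type or labelled as global knockouts of Fndc5, the precursor of the exercise hormone irisin, and lived with a running wheel or without (sedentary). There were 4 wild-type running, 4 wild-type sedentary, 4 knockout running and 5 knockout sedentary mice, each with 1 library.

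The total count per library was 6.03e+06 ± 2.48e+06 (SD, n = 4) in wild-type running mice (3.49e+06 to 8.52e+06) and 2.01e+06 ± 8.42e+05 (n = 4) in wild-type sedentary mice (1.08e+06 to 2.87e+06). It was 2.92e+06 ± 4.69e+05 (n = 4) in knockout running mice (2.40e+06 to 3.54e+06) and 3.21e+06 ± 5.81e+05 (n = 5) in knockout sedentary mice (2.28e+06 to 3.83e+06). Between 14888 and 17447 genes had a count per library, and 13005 were tested. Malat1, an abundant long non-coding RNA retained in the nucleus, took 21.6% ± 1.47 of all counts in wild-type libraries (SD, n = 8) and 27.6% ± 0.848 in libraries labelled knockout (n = 9). The difference of 6.01 points had a two-sided exact permutation p of 4.11e-05, the smallest that 24310 splits allow, with the 17 libraries taken as independent.

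Mice of the same genotype gave counts that differed by little more than counting noise except in the most abundant genes, whichever housing they came from. The index of pairwise differences, which is 1 for counting noise alone, had a median of 1.08 over 28 pairs of mice from the same group and 1.07 over 36 pairs of the same genotype but other housing, both without Malat1. Within a group the median was 1.18 in wild-type (highest 1.5) and 1.06 in knockout-labelled mice (highest 1.37), and across housing 1.11 (highest 1.40) and 1.055 (highest 1.253). Over 72 pairs of different genotype it was 2.39 (lowest 1.80). The biological coefficient of variation fitted with the 4 groups was 2.59%, against 6.80% when the groups were left out of the fit. With Malat1 included, all 64 pairs within a genotype differed from 1 (largest p = 0.0198, chi-square test). Without Malat1, 3 of the 64 pairs did not differ from 1 by the same test. Of the same group these were knockout running mice 1 and 4 (index 1.02, chi-square p = 0.0600). Across housing they were knockout running mouse 4 with sedentary mouse 2 (1.014, chi-square p = 0.142) and running mouse 3 with sedentary mouse 5 (1.017, chi-square p = 0.0935). The genotype p-values are measured against this small spread, and like the permutation tests they take the 17 libraries as independent, which the table cannot show.

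**Figure D1:**
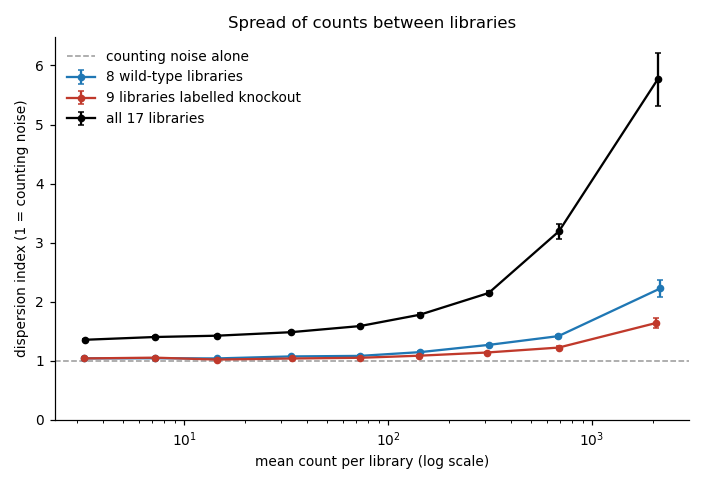
Dispersion index (y axis, 1 = counting noise alone) against the mean count per library (x axis, log scale), as means over genes with the standard error as bars, for the 8 wild-type libraries, the 9 libraries labelled knockout and all 17. Within a genotype the index was 1.04 for genes with 2 to 5 counts, against 1.36 for all libraries together. Above 1000 counts it was 2.23 in wild-type libraries, 1.64 in libraries labelled knockout and 5.77 for all.

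Fndc5 itself was not lower in the libraries labelled knockout. Its level was 33.04 CPM ± 2.40 (SD, n = 9) there and 26.0 CPM ± 2.77 (n = 8) in wild-type libraries, which is 1.27-fold higher (edgeR adjusted p = 9.25e-05), and each of the 9 lay above the wild-type mean. In the libraries of all 4 groups the values ran from 21.1 to 36.7 CPM. Fndc5 (ENSMUSG00000001334) lies on chromosome 4 of mm10 from 129136999 to 129144593 on the plus strand, and 0 other annotated genes share its 2763 bases of exon. The exact permutation p was 4.11e-05 over all mice, 0.00794 in sedentary, 0.0286 in running mice and 0.00794 within the middle run of sample identifiers, each the smallest its splits allow, with the libraries taken as independent. In that run alone edgeR gave an adjusted p of 0.0994. Counts per exon were not in the table, so whether reads came from a deleted part of the gene is unknown.

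**Figure D2:**
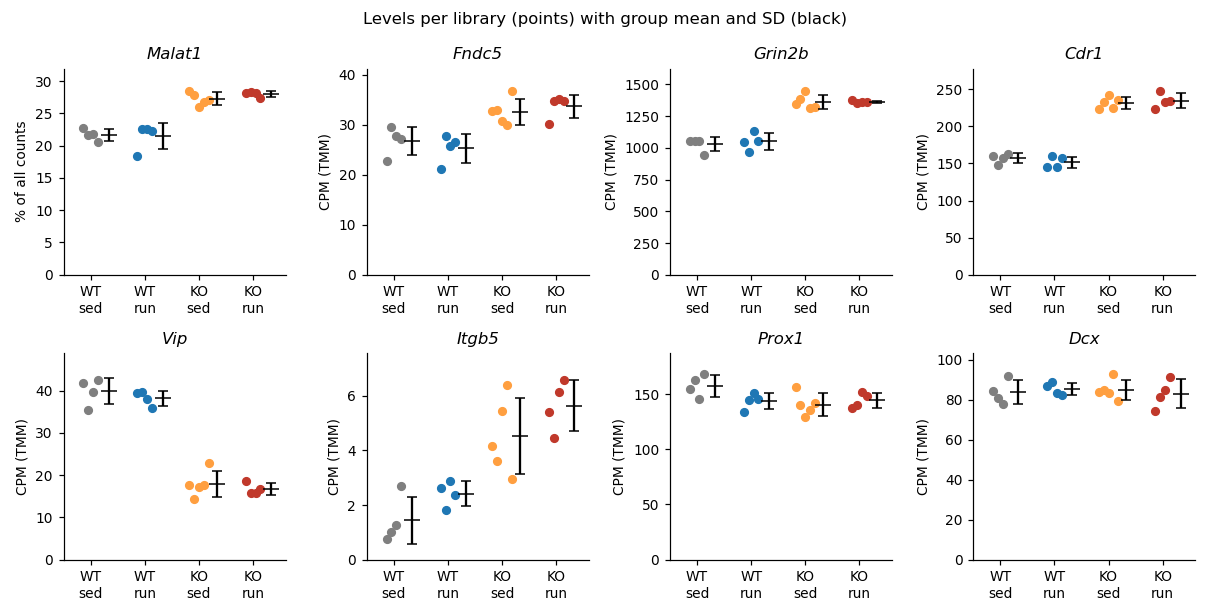
Levels per library (points) in the 4 groups, with group mean and SD (black), as % of all counts for Malat1 and as CPM with TMM scaling for 7 genes. Vip was lower and Malat1, Cdr1, Grin2b and Itgb5 were higher in libraries labelled knockout in both housings, while Dcx lay near 84 CPM in all groups.

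The comparison of running with sedentary wild-type mice asks what wheel running changed in newborn neurons. Genes that mark these cells had similar levels in both groups. Dcx, the marker of young neurons, was at 85.5 CPM ± 3.17 in running and 83.8 CPM ± 6.09 in sedentary mice (log2 fold change 0.03), and Bdnf, the neurotrophin, at 68.4 ± 5.51 and 62.3 ± 6.18 CPM (0.08). Prox1, the transcription factor of granule cells, was at 144 ± 7.10 and 158 ± 9.80 CPM, with adjusted p = 0.953 for its log2 fold change of -0.12. The lowest p belonged to Atm, the DNA damage kinase, at 106 ± 3.85 CPM in running and 127 ± 13.4 CPM in sedentary mice (adjusted p = 0.769, with all 4 running mice below the sedentary mean). Cidea, a lipid droplet protein, was at 2.57 ± 0.444 CPM in running (64 counts) and 0.569 ± 0.898 CPM in sedentary mice (4 counts), a 5.01-fold difference that did not pass (adjusted p = 0.769).

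By edgeR's quasi-likelihood test 0 of 13005 genes passed in wild-type mice, with 668 at an unadjusted p under 0.05, where chance gives 650. DESeq2 also called 0, with 336. Other genes with low p that did not pass included the splicing factor Srsf9 (log2 fold change 0.20), Aplp2 of the amyloid precursor family (0.14), Creb3 (0.27), the chemokine Cxcl12 (-0.60) and the chromatin remodelling subunit Smarcd2 (-0.38). Next by p, and not past the threshold, came 4930578G10Rik, Ldhd, Clptm1, Abca2, Klhdc8b and Pnp on the higher side and Mpped1, Aftph, Elovl6, Ring1, Dhx9, Smc1a and Taf9b on the lower side. Itgb5 (2.02-fold, adjusted p = 0.953), Itgav and Fndc5 did not pass either. None of the 29 gene lists passed (smallest camera adjusted p = 0.330), while without wild-type running mouse 3 the glycolysis and lactate list did, as higher (adjusted p = 0.0166). Adjusted over the list alone, 1 gene each passed in the pyramidal neuron (lower) and interneuron (higher) lists. The median 95% confidence interval for the 8091 genes above 16 CPM reached 0.18 on the log2 scale to either side. In simulated counts at this depth, 29 of 29 genes above 16 CPM with a 1.5-fold change and 16 of 31 with a 1.25-fold change were found. The simulation drew independent libraries with the spread fitted to these data, so it does not cover material shared across housing. Leaving out wild-type sedentary mouse 2 brought 1 gene past the threshold, Atm, and a term for the runs of identifiers brought 1.

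In knockout-labelled mice, whose libraries held Fndc5 reads, the same comparison asks what wheel running changed. Here too the markers were alike: Dcx stood at 83.0 CPM ± 7.13 in running and 85.0 ± 4.93 in sedentary mice, Prox1 at 144 ± 6.72 and 140 ± 10.1, and Bdnf at 62.4 ± 7.93 and 65.5 ± 4.92. The lowest p belonged to Cdyl2, a chromodomain protein, at 10.2 CPM ± 1.07 in running and 15.8 ± 1.32 in sedentary mice (1.55-fold lower, adjusted p = 0.906). Icam5, a dendritic adhesion molecule, was at 57.5 ± 4.44 and 70.7 ± 4.96 CPM with the same adjusted p. Rbpj, the transcription factor of Notch signalling, was at 21.5 ± 2.89 and 16.1 ± 1.14 CPM (adjusted p = 0.999).

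By edgeR 0 of 13005 genes passed in knockout-labelled mice, with 553 at an unadjusted p under 0.05, and by DESeq2 0, with 262. The kinase Cdk14 (log2 fold change 0.17), Ssr3 (0.26), Lin37 (-0.32) and the mitochondrial chaperonin Hspd1 (-0.45) were among the next genes by p. The others, which did not pass, were Zfp512b, Hsbp1, Tmem192, Zfp37, C3ar1, Ephb2 and St5 on the higher side and Ipmk, Klhdc10, Maz, Xrcc1, Gm15246 and Rspo3 on the lower side. Itgb5, Itgav and Fndc5 did not pass. The smallest camera adjusted p of the 29 lists was 0.253, shared by the astrocyte and the autophagy and lysosome lists. Adjusted over the list alone, 1 gene passed as higher in the Notch and Wnt list and 1 as lower in the heat shock list. With fry's mixed test, which asks whether genes of a list change in either direction, Notch and Wnt signalling had an adjusted p of 0.0177, and with fry's directional test 0.873. Within the middle run of sample identifiers alone, which holds 3 running and 1 sedentary knockout mice, 1 gene passed, with the lone library assumed to vary like the other groups.

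The difference between genotypes in the running effect asks whether running acts otherwise in mice labelled knockout. The genes with the lowest p were Icam5, whose running effect was lower by 0.49 on the log2 scale in knockout-labelled than in wild-type mice, and Cidea, at 1.78 ± 1.59 CPM in knockout running and 3.30 ± 1.33 in knockout sedentary mice (20 and 49 counts) against 2.57 ± 0.444 and 0.569 ± 0.898 CPM in wild type (64 and 4 counts). Both had an adjusted p of 0.155. Mpped1 followed on the higher side (log2 0.34, adjusted p = 0.570), and Atg12 of the autophagy machinery (-0.51) and Cdyl2 (-0.86) on the lower side with the same adjusted p. For Dcx, Prox1 and Bdnf the differences were -0.07, 0.16 and -0.16 (adjusted p = 0.994 each). Pdcd10, Nnt, Dpy19l3, Adprh, Tmem192, Syne2, C3ar1, Smarcd2 and Adam17 on the higher side and Klhdc10, Hapln2, Zc4h2, Ccdc9, Kat7 and Pan3 on the lower side followed by p and did not pass, nor did Fndc5, Itgb5 and Itgav.

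By edgeR 0 genes passed for this difference, with 600 at an unadjusted p under 0.05, and by DESeq2 0, with 325. In counts simulated in the same way 29 of 36 genes above 16 CPM with a 1.5-fold difference and 7 of 31 with a 1.25-fold difference were found. The smallest camera adjusted p of any list was 0.476. Adjusted over the list alone, 1 gene passed in the pyramidal neuron list (higher) and 1 in the autophagy list (lower). Cidea passed with limma voom, with quality weights for libraries, without wild-type sedentary mouse 3 and without knockout running mouse 4. Across the 13005 genes, which are not independent replicates, the running effects in the 2 genotypes had a Pearson correlation of -0.0083 and a Spearman correlation of -0.0046. Regrouping the mice between housings within each genotype gave Pearson values from -0.0455 to 0.0452. With the runs of sample identifiers as a covariate the Pearson correlation was 0.20 and the Spearman correlation 0.18. The regroupings were made without that covariate, so their range does not apply to these values. In that fit both running effects were adjusted by the same estimated differences between runs, and the first run held sedentary mice only. The 2 effects are then not separate estimates and cannot be read as a shared response. The cause was not tested.

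**Figure D3:**
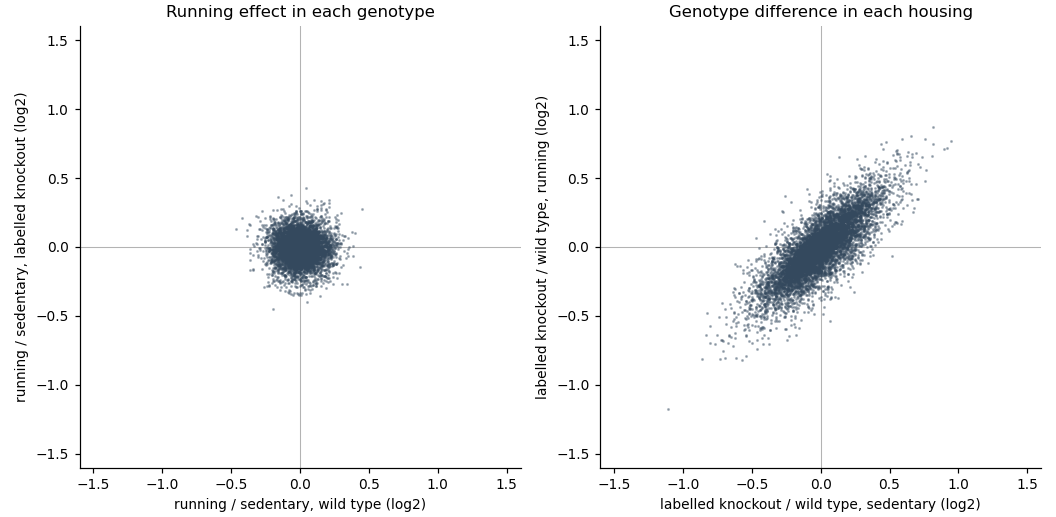
Left, log2 fold change of running against sedentary in wild-type (x axis) and knockout-labelled mice (y axis). Right, log2 fold change of labelled knockout against wild type in sedentary (x axis) and running mice (y axis), for the same 8093 genes with a mean of at least 16 CPM (points), with Pearson correlations across genes of -0.0112 on the left and 0.807 on the right.

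Averaged over genotype, running and sedentary mice were likewise compared. Clptm1, a membrane protein, was at 27.7 CPM ± 3.31 in running (n = 8) and 21.6 ± 5.03 in sedentary mice (n = 9), with an adjusted p of 0.504 in edgeR. Creb3 (log2 fold change 0.20), Tas1r3 (0.62), Cntn3 (0.16), Sox8 (0.39), Cercam (-0.74), Lin37 (-0.22), Atm (-0.15), AF357425 (-0.25) and Hspd1 (-0.32) had the next lowest p, each with an adjusted p of 0.973. Dcx was at 84.3 ± 5.27 and 84.5 ± 5.14 CPM. By edgeR 0 genes passed, with 610 at an unadjusted p under 0.05, and by DESeq2 0, with 331. The smallest camera adjusted p of the lists was 0.144, shared by glycolysis and lactate, the heat shock response, and autophagy and lysosome, and adjusted over the list alone 1 heat shock gene passed as lower. Without wild-type running mouse 3 the glycolysis and lactate list passed as higher (adjusted p = 0.0168). Within the middle run of identifiers, with 1 knockout-labelled sedentary library assumed to vary like the other groups, 1 gene passed.

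In sedentary mice, the comparison of knockout-labelled with wild-type neurons asks what goes with the knockout label at rest. Many genes differed by a little and a few weakly expressed genes differed by much. Zbtb9, a zinc finger protein, was at 4.41 CPM ± 1.13 in knockout-labelled mice (71 counts, n = 5) and 0.508 ± 0.619 in wild type (4 counts, n = 4), an 8.83-fold difference. Pfkfb1, an enzyme that sets the level of fructose 2,6-bisphosphate, was 8.08-fold higher (5.35 ± 1.93 against 0.660 ± 0.243 CPM). Ttr, the thyroid hormone carrier made by the choroid plexus, was 7.18-fold higher (2.76 ± 1.08 against 0.264 ± 0.326 CPM, 44 against 3 counts). Nox4, an NADPH oxidase, was 14.55-fold lower (0.186 ± 0.274 against 4.20 ± 3.34 CPM, 3 against 27 counts), and Greb1, known as an oestrogen response gene, was 7.56-fold lower (0.321 ± 0.207 against 2.47 ± 1.11 CPM).

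The other genes with the largest changes also lay below 6 CPM in both genotypes. The rise was 6.29-fold for the protease Tmprss7, 6.12-fold for Cidea, 5.28-fold for Cd59a and 5.17-fold for the potassium channel subunit Kcns1, and 9430037G07Rik, Mmp21 and Hyal3 rose between 4.57- and 5.63-fold. The fall was 6.18-fold for the protease Tmprss5, 5.10-fold for the glycogen phosphorylase Pygl and 4.47-fold for the neuropeptide gene Pnoc. E130114P18Rik, Efcab3, Zim1 and Cfap43 fell between 4.15- and 5.22-fold. In each of these genes all 5 knockout-labelled libraries lay on the same side of the wild-type mean, which their choice by size of change in the same libraries favours. Itgb5, the integrin subunit that with Itgav forms a receptor described for irisin, was 3.63-fold higher (4.52 ± 1.39 against 1.44 ± 0.871 CPM, adjusted p = 0.000386), while Itgav, Dcx and Bdnf did not pass. Prox1 was 1.13-fold lower (adjusted p = 0.0180, not past the threshold with quantile normalization, where the adjusted p was 0.0947).

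By edgeR 2954 of 13005 genes passed in sedentary mice, 1376 higher and 1578 lower in knockout-labelled libraries, with a median absolute log2 fold change of 0.37. With library totals in place of TMM, chosen after seeing the data, 705 were higher and 2685 lower. Of cytosolic ribosomal protein genes 10 of 39 rose, 0 fell and 29 did not pass (median log2 0.20, camera adjusted p = 0.0254), with an adjusted p of 0.429 with an estimated correlation. The list did not pass when any 1 of 3 of the 17 mice was left out (largest adjusted p = 0.0765). In axon guidance and dendrite growth 10 of 29 rose and 1 fell (camera adjusted p = 0.0983, and 0.0408 without wild-type sedentary mouse 4). Of cell type markers, 5 of 19 oligodendrocyte genes rose and 1 fell, 2 of 11 oligodendrocyte precursor genes rose, 3 of 18 astrocyte genes rose, 3 of 17 endothelial and mural genes rose, and 1 of 15 microglial genes fell. Of pyramidal neuron genes 5 of 20 rose and 2 fell, of interneuron genes 3 of 17 rose and 6 fell, of immature granule neuron genes 3 of 22 rose and 1 fell, and of mature granule neuron genes 0 of 20 rose and 4 fell. With library totals the genes higher and lower were 3 and 0 for ribosomal proteins, 5 and 6 for axon guidance, 3 and 2 for oligodendrocyte, 1 and 2 for oligodendrocyte precursor, 1 and 2 for astrocyte, 0 and 1 for microglial, 2 and 0 for endothelial and mural, 2 and 4 for pyramidal neuron, 2 and 7 for interneuron, 1 and 4 for immature and 0 and 10 for mature granule neuron genes. Within the middle run of identifiers, with 1 knockout-labelled and 2 wild-type sedentary libraries, 714 genes passed, of which 631 were among the 2954, and there the lone library was assumed to vary like the other groups. Of the genes named for the largest changes, Zbtb9, Pfkfb1, Cidea, 9430037G07Rik, Cd59a, Kcns1, Hyal3, Greb1, Efcab3, Pygl, Pnoc, Zim1 and Cfap43, and Itgb5 and Prox1, did not pass in that run alone, and Cfap43 not without wild-type sedentary mouse 2.

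In running mice the same comparison asks what goes with the knockout label under exercise. Hyal3, a member of the hyaluronidase family, was 7.03-fold higher in knockout-labelled mice (3.34 CPM ± 0.800 against 0.397 ± 0.315, n = 4 each). Ttr was 6.22-fold higher (4.87 ± 2.38 against 0.683 ± 0.298 CPM), and Dock8, a guanine nucleotide exchange factor, 5.45-fold higher. Nox4 was 6.62-fold lower (0.383 ± 0.517 against 2.60 ± 0.204 CPM, 4 against 64 counts), and Esr1, the oestrogen receptor alpha, 4.13-fold lower (1.43 ± 0.604 against 6.05 ± 0.674 CPM). Gm14023, B430319G15RIK, Zbtb9, Phex, Xrcc2, Rarres1 and Zfp217 rose between 3.43- and 4.30-fold. Tmprss5, Scrn2, Greb1, Pygl, Nid1, Serpinb9, Gsdmd and Zim1 fell between 3.72- and 5.25-fold. Itgb5 was 2.22-fold higher (adjusted p = 0.000403), and Dcx, Prox1, Bdnf and Itgav did not pass.

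By edgeR 3915 genes passed in running mice, 1893 higher and 2022 lower, with a median absolute log2 fold change of 0.35. With library totals in place of TMM, chosen after seeing the data, 903 were higher and 3851 lower. Of the ribosomal protein genes 11 of 39 rose and 0 fell (13 adjusted over the list alone), with a camera adjusted p of 0.114 and 0.388 with an estimated correlation. Of oxidative phosphorylation genes 12 of 38 rose and 1 fell, of astrocyte genes 5 of 18 rose, of oligodendrocyte genes 5 of 19 rose and 1 fell, of oligodendrocyte precursor genes 3 of 11 rose and 1 fell, and of microglial genes 2 of 15 rose and 1 fell. Of endothelial and mural genes 5 of 17 rose and 2 fell, of pyramidal neuron genes 5 of 20 rose and 3 fell, of interneuron genes 2 of 17 rose and 6 fell, of immature granule neuron genes 3 of 22 rose and 1 fell, and of mature granule neuron genes 0 of 20 rose and 2 fell. With library totals the genes higher and lower were 2 and 4 for ribosomal proteins, 3 and 7 for oxidative phosphorylation, 2 and 3 for astrocyte, 2 and 3 for oligodendrocyte, 3 and 3 for oligodendrocyte precursor, 2 and 2 for microglial, 4 and 2 for endothelial and mural, 4 and 4 for pyramidal neuron, 2 and 7 for interneuron, 3 and 5 for immature and 0 and 11 for mature granule neuron genes. In both housings 945 genes were higher, where independent lists would share 200, and 1103 were lower, where they would share 245. Of the genes called in sedentary mice 97.8% had the same sign in running mice. Across genes, which are not independent replicates, the genotype effects of the 2 housings had a Pearson correlation of 0.75 and a Spearman correlation of 0.73. The 2 comparisons share no library, but whether they share material within a genotype is unknown. Libraries of a genotype were nearly alike across housing, and shared material would also give this agreement. Within the middle run of identifiers 2821 genes passed, of which 2677 were among the 3915.

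Averaged over housing, Malat1 was 1.37-fold higher in libraries labelled knockout than in wild type. Cdr1 rose from 154 CPM ± 7.23 in wild type (n = 8) to 233 ± 8.28 (n = 9), a 1.52-fold difference. Grin2b, the GluN2B subunit of the NMDA receptor, rose from 1039 ± 58.2 to 1363 ± 40.02 CPM, and the adhesion genes Ntm and Il1rapl1 rose 1.35- and 1.34-fold. Vip, the neuropeptide that marks a class of interneurons, fell 2.21-fold, from 39.0 ± 2.49 to 17.4 ± 2.42 CPM. Col19a1, a collagen, fell 1.33-fold, Trank1 1.30-fold, the LIM protein Fhl1 1.38-fold and the splicing regulator Hnrnph1 1.26-fold. All 9 libraries labelled knockout lay on the same side of every wild-type library for these 10 genes. The genes were picked by their p in the same libraries, so this separation is not further support. The adjusted p was 2.81e-47 for Malat1, 1.18e-39 for Cdr1, 1.46e-39 for Grin2b and 1.55e-28 for Vip.

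In mm10 the annotation places Malat1 (ENSMUSG00000092341) on chromosome 19 from 5795690 to 5802672, Cdr1 (ENSMUSG00000090546) on chromosome X from 61184005 to 61185558, Grin2b (ENSMUSG00000030209) on chromosome 6 from 135713233 to 136173511 and Vip (ENSMUSG00000019772) on chromosome 10 from 5639218 to 5647617. Itgb5 (ENSMUSG00000022817) lies on chromosome 16 from 33829665 to 33949338, Prox1 (ENSMUSG00000010175) on chromosome 1 from 190118035 to 190170714, Zbtb9 (ENSMUSG00000079605) on chromosome 17 from 26973167 to 27008376 and Nox4 (ENSMUSG00000030562) on chromosome 7 from 87246096 to 87398710. Of the genes named for running, Atm (ENSMUSG00000034218) lies on chromosome 9 from 53439149 to 53536740, Cidea (ENSMUSG00000024526) on chromosome 18 from 67343604 to 67367785, Cdyl2 (ENSMUSG00000031758) on chromosome 8 from 116574400 to 116732991 and Icam5 (ENSMUSG00000032174) on chromosome 9 from 21032073 to 21039036.

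By edgeR 5509 of 13005 genes passed in the averaged comparison (42.4%), 2680 higher and 2829 lower, with a median absolute log2 fold change of 0.30. Of these 231 changed more than 2-fold. The share called rose with the level, from 32.8% of genes between 1 and 4 CPM to 64.2% of those above 256 CPM, while the median absolute change of called genes fell from 0.94 to 0.13. Malat1 weighs on the scaling. With library totals in place of TMM, chosen after seeing the data, the median of all genes moved to -0.10, and 1478 genes were higher and 4690 lower. Quantile normalization sets Malat1 at 0 by construction, since it ranks highest in every library. Within the middle run of identifiers, where knockout-labelled sedentary mice had 1 library, 2748 genes passed, of which 2569 were among the 5509. The exons of Malat1, Cdr1 and Grin2b overlap annotated transcripts of the opposite strand (C230004F18Rik for Cdr1), and the strand counted was not stated.

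Among neuronal lists in the averaged comparison, glutamate receptor and scaffold genes moved both ways: 11 of 25 rose, such as Grin2b, and 7 fell, such as Gria3 (900 ± 16.04 against 1050 ± 36.0 CPM). Of presynaptic genes 4 of 25 rose and 6 fell, with the calcium sensor Syt1 higher (log2 fold change 0.21) and Syn3 1.48-fold lower. Of GABA receptor and chloride transport genes 4 of 17 rose and 5 fell, with the subunits Gabrb1 and Gabra3 higher by 1.30- and 1.80-fold. Of voltage-gated channel genes 6 of 23 rose and 6 fell, with Cacna2d1 1.14-fold lower. In axon guidance and dendrite growth 11 of 29 rose, such as Dscam (1.43-fold) and Mapt, which encodes tau (1.17-fold), and 2 fell, with a camera adjusted p of 0.130. Of BDNF and CREB signalling genes 7 of 22 rose, such as the BDNF receptor Ntrk2 (1.23-fold) and the kinase subunit Camk2b (1.14-fold), and 7 fell. Bdnf itself did not pass. Of the immediate early genes 3 of 18 rose, Nr4a2 and Nr4a3 by 1.23- and 1.22-fold, and 3 fell. Of the irisin receptor integrin and focal adhesion genes 3 of 14 rose and 3 fell, with Itgb5 at 5.01 ± 1.28 against 1.93 ± 0.833 CPM (2.84-fold) and the adhesion protein Tln2 1.22-fold higher.

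The cell type markers that passed in the averaged comparison are counted next. Of all 13005 genes 42.4% passed there, 2680 higher and 2829 lower, so such counts arise in lists of any kind. None of the cell type lists passed camera. Of immature granule neuron genes 4 of 22 rose, such as Gap43 and Camk4 (1.33- and 1.16-fold), and 3 fell, and Dcx did not pass (84.1 ± 5.68 against 84.7 ± 4.58 CPM). Of mature granule neuron genes 0 of 20 rose and 5 fell, among them Stxbp6 (1.36-fold) and Rfx3 (1.07-fold), and Prox1 had a log2 fold change of -0.09 (adjusted p = 0.0405, not past the threshold with DESeq2 at 0.111, nor when any of 8 of the mice was left out). Of pyramidal neuron genes 6 of 20 rose, such as Pex5l and Man1a (1.32- and 1.49-fold), and 4 fell. Of interneuron genes 3 of 17 rose, such as the neuregulin receptor Erbb4 (1.41-fold), and 7 fell, such as Vip. Of oligodendrocyte genes 6 of 19 rose, such as the myelin genes Mbp and Mal (1.26- and 1.30-fold), and 2 fell. Their summed level was 1584 CPM ± 29.8 in libraries labelled knockout and 1523 ± 21.4 in wild type. In the same order it was 1773 ± 35.4 and 1869 ± 39.4 CPM for mature granule neuron genes and 117.6 ± 7.24 and 127.6 ± 10.9 for microglial genes. For endothelial and mural genes it was 103.5 ± 4.83 and 91.2 ± 5.54 CPM. It was 1489 ± 15.9 and 1482 ± 24.6 CPM for immature granule neuron genes and 1137 ± 24.0 and 1082 ± 18.8 for pyramidal neuron genes. For interneuron genes it was 1179 ± 17.3 and 1246 ± 29.0 CPM, and for astrocyte genes 1030 ± 24.0 and 983 ± 8.84. These levels rest on TMM scaling. The lists hold different genes, so their sums do not measure how pure the sorted nuclei were. Of oligodendrocyte precursor genes 3 of 11 rose, such as Tnr and Olig1 (1.37- and 1.57-fold), and 1 fell, and of astrocyte genes 5 of 18 rose, such as Slc4a4 and Mlc1 (1.20- and 1.72-fold), and 1 fell. Of endothelial and mural genes 6 of 17 rose, such as Ly6a and Vtn, and 1 fell, and of microglial genes 2 of 15 rose, P2ry12 and Cx3cr1, and 2 fell. Of stem and cycling cell genes 1 of 11 rose (Pcna) and 1 fell, and of the 4 choroid plexus and ependymal genes that were tested 1 rose and 1 fell. The glial and vascular counts stood beside the changes of neuronal genes in the same libraries.

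Of ribosomal protein genes 17 of 39 rose, 0 fell and 22 did not pass in the averaged comparison, with those that rose including Rps20 (40.6 ± 3.47 against 30.4 ± 2.22 CPM) and Rps19 (1.26-fold). The camera adjusted p was 0.0328, and 0.494 with an estimated correlation, and the list did not pass when any 1 of 4 of the 17 mice was left out (largest adjusted p = 0.0788). With fry's directional test, which asks whether the genes of a list move on balance in the same direction and does not compare them with other genes, the adjusted p was 0.000363. With library totals 10 rose and 5 fell, at a median of 0.06 against -0.10 for all genes. These genes have processed pseudogenes whose reads the table cannot separate. Of oxidative phosphorylation genes 13 of 38 rose, such as Cox4i1 and Ndufa4 (1.29- and 1.23-fold), and 4 fell (camera adjusted p = 0.148). With library totals 4 rose and 13 fell in that list, 7 rose and 10 fell in axon guidance, 5 rose and 13 fell among glutamate receptor genes, and 3 rose and 3 fell among astrocyte genes. Of the 29 lists, ribosomal proteins alone passed camera with the preset correlation, and 0 passed with an estimated correlation. For several lists that did not pass, such as immediate early genes (-0.01) and BDNF and CREB signalling (-0.04), the median log2 fold change was below 0 while the direction of the test was up.

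The other process lists but p53 and apoptosis held both higher and lower genes. Of chromatin regulators 6 of 30 rose, such as the remodeller Chd4 (1.21-fold), and 7 fell, such as Arid1b (66.3 CPM ± 4.41 in libraries labelled knockout). Of Notch and Wnt genes 6 of 26 rose, such as Gsk3b and Wnt5a (1.26- and 1.53-fold), and 2 fell. Of interferon and inflammatory genes 3 of 10 rose, such as the NF-kappaB inhibitor Nfkbia (1.88-fold) and B2m (1.22-fold), and 1 fell. Of heat shock and unfolded protein genes 5 of 20 rose, such as the chaperone Hspa5 and the sensor Atf6 (1.21- and 1.20-fold), and 2 fell. Of glycolysis genes 5 of 20 rose (Hk1, 1.29-fold) and 5 fell (Gpi1, 1.14-fold), of cholesterol synthesis genes 2 of 19 rose and 4 fell, such as Sc5d and Fdft1, and of autophagy and lysosome genes 1 of 23 rose (Gabarap, 1.26-fold) and 2 fell. Of p53 and apoptosis genes 0 of 13 rose and 2 fell (Mdm2 and Trp53, 1.14- and 1.28-fold). Of nuclear retained RNAs 4 of 13 rose, such as Malat1, and 4 fell, such as Ftx (324 ± 17.1 against 383 ± 12.4 CPM).

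With library totals the counts of genes higher and lower in the averaged comparison were 1 and 13 for presynaptic genes, 3 and 9 for GABA receptor genes, 4 and 13 for voltage-gated channels, 5 and 9 for BDNF and CREB signalling, 2 and 6 for immediate early genes and 3 and 5 for integrin and focal adhesion genes. They were 3 and 7 for immature and 0 and 13 for mature granule neurons, 5 and 5 for pyramidal neurons, 2 and 9 for interneurons, 5 and 3 for oligodendrocytes, 3 and 3 for their precursors, 4 and 2 for endothelial and mural cells, 2 and 4 for microglia, and 1 and 1 each for stem and cycling cells and for choroid plexus. They were 2 and 9 for chromatin regulators, 3 and 2 for Notch and Wnt genes, 2 and 1 for interferon genes, 2 and 7 for heat shock genes, 4 and 9 for glycolysis, 0 and 7 for cholesterol synthesis, 1 and 9 for autophagy, 0 and 3 for p53 and apoptosis, and 2 and 7 for nuclear retained RNAs.

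Adjusted over the list alone, the counts of genes higher and lower were 12 and 9 for glutamate receptor genes, 5 and 8 for presynaptic genes, 6 and 7 for voltage-gated channels, 11 and 3 for axon guidance, 8 and 7 for BDNF and CREB signalling, and 14 and 4 for oxidative phosphorylation. They were 0 and 4 for mature granule neurons, 2 and 1 for interferon genes, 5 and 2 for Notch and Wnt genes, 2 and 2 for cholesterol synthesis, and as over all genes for the other 19 lists. Of the list members named, Camk4, Tln2, Nr4a3, Ly6a, P2ry12, Cx3cr1, Pcna, B2m, Gpi1, Sc5d and Gabarap did not pass within the middle run of identifiers alone. For Gpi1 the adjusted p was 0.0611 with DESeq2.

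**Figure D4:**
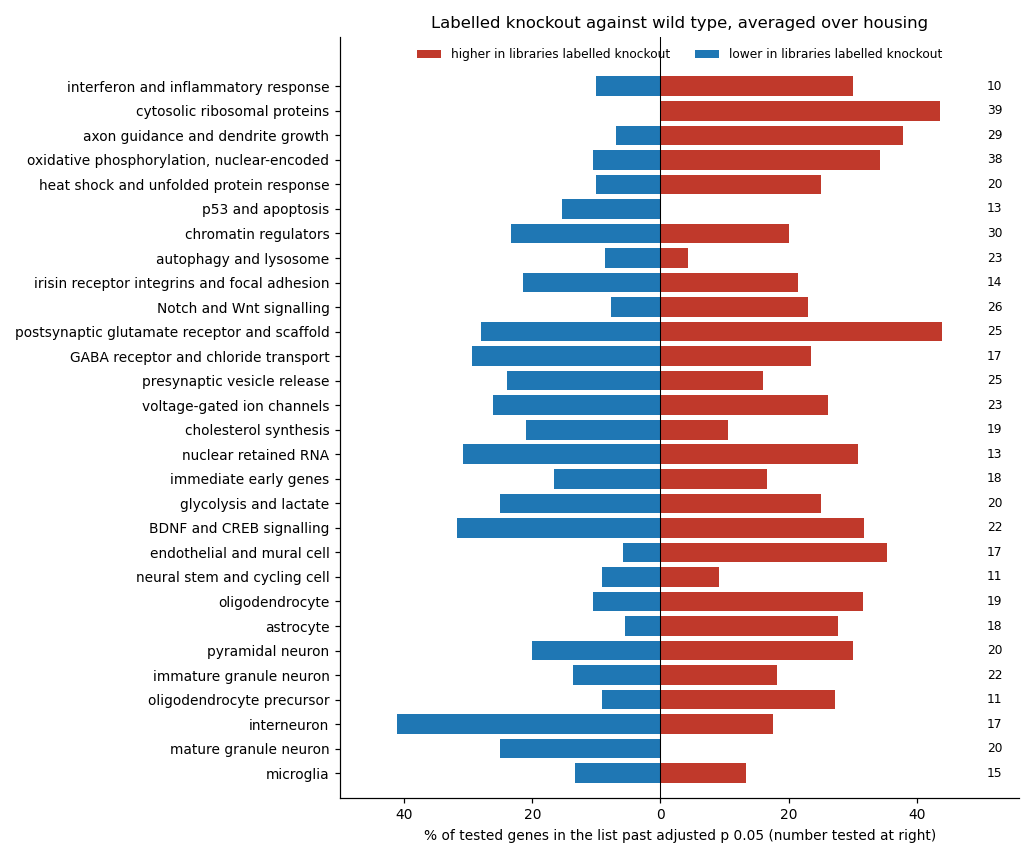
Share of the tested genes of each list (y axis) that passed an adjusted p of 0.05 in the averaged genotype comparison, in % (x axis), higher (red, to the right) and lower (blue, to the left) in libraries labelled knockout, with TMM scaling. In the ribosomal protein list 17 of 39 genes were higher and 0 lower, while with library totals 10 were higher and 5 lower.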

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

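The library measures and genes tested for a library far from its group were 5 measures, chosen after their values were seen, and 26 genes, those the rule names always or in the averaged comparisons. A library stood apart where its gap to the nearest of the others exceeded Dixon's 95% critical value, which chance gives in about 6.2 of the 124 groups tested, and 12 were found. None of them was weighed further.

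Knockout running mouse 4 had a Malat1 share of 27.33% of counts where the others had 28.18 to 28.25%. Its 50 most abundant genes took 35.56% where the others had 36.39 to 36.46%, and its Malat1 level was 281900 CPM where the others had 294700 to 296500. Wild-type running mouse 1 had a Malat1 share of 18.4% where the others had 22.26 to 22.62%. Its 50 most abundant genes took 27.58% against 31.09 to 31.52%, and its Malat1 level was 169600 CPM against 214800 to 221100. Malat1 weighs on all 3 measures, so they are not separate results.

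Fndc5 was at 30.18 CPM in knockout running mouse 1 and at 34.62 to 35.05 CPM in the other mice of its group. Creb3 was at 39.74 CPM in knockout sedentary mouse 1 (others 43.84 to 45.18). In knockout sedentary mouse 4, Sox8 was at 10.96 CPM (others 14.46 to 15.25) and AF357425 at 32.27 CPM (others 40.67 to 43.98). In wild-type sedentary mouse 4, Grin2b was at 947.6 CPM (others 1053 to 1058) and Cercam at 9.025 CPM (others 4.244 to 5.035).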

How the results depend on the processing

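The genotype counts held under most settings, though with library totals, chosen after seeing the data, the averaged comparison had 1478 genes higher and 4690 lower, and the running comparisons had 0 or 1 genes past the threshold under all. Within the middle run of identifiers alone, with fewer mice, 714 genes passed in sedentary mice and 2748 in the averaged genotype comparison, and 1 gene passed for running in knockout-labelled mice and 1 averaged over genotype, with the lone knockout-labelled sedentary library assumed to vary like the other groups. With the runs as a covariate 1 gene passed for running in wild type, and the correlation of the running effects was 0.20. Both effects were adjusted there by the same estimated differences between runs, and the cause was not tested. For the difference in the running effect 1 gene (Cidea) passed with library quality weights and 1 (Cidea) with limma voom, the latter chosen after seeing the data. Over all comparisons 2 list calls passed camera, 0 with an estimated correlation and 41 with fry's directional test, which asks another question.

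With each mouse left out in turn, genes past the threshold ranged from 0 to 1 for running in wild type, 0 to 0 in knockout-labelled mice, 2127 to 3001 for genotype in sedentary mice, 3097 to 3982 in running mice, 0 to 1 for the difference in the running effect, 4959 to 5433 for genotype averaged and 0 to 0 for running averaged. Lists past the threshold ranged from 0 to 3, the Fndc5 difference in log2(CPM + 1) from 0.296 to 0.362 and the correlation from -0.0151 to 0.000725. DESeq2 called 2036, 2610 and 4545 genes for genotype in sedentary mice, in running mice and averaged. Of 352 called values of named genes 195 kept their call in every setting that gave them a value, 157 lost it in at least 1, and 1 reversed. The stricter filter and the fit of only the groups compared left some without a value, and 163 had one in all 15 settings. The reversed value was Gpi1 in sedentary mice, at 0.13 within the middle run (adjusted p = 0.590); the cause was not tested.

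No pairing of the libraries by mouse number was seen. Over 24 pairs with the same number the median correlation of deviations was -0.00601, and 0 exceeded 0.1. Over 84 pairs with other numbers the median was 0.00211, and 0 exceeded 0.1. Of 16 libraries 2 correlated best with their own number. Most of these deviations were counting noise, which keeps any such correlation small, so pairing is not excluded. With the number as a replicate block 2492, 3766 and 5318 genes passed for genotype in sedentary mice, in running mice and averaged, and 0 for running. The pseudocount and recomputed TMM alternatives did not apply to counts already scaled by TMM, except for Fndc5 on the log scale. Quantile normalization holds Malat1 at 0 by construction. Depth limited weakly expressed genes: of simulated 1.5-fold changes in wild-type running mice 66% were found.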

Other observations

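The tests of library likeness and of genotype spread, and all the explanations weighed, were chosen after the result was seen, while the list of sex-linked genes and the regroupings of mice were planned.

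Beyond counting noise within a genotype, 0.984% of 13005 genes varied in wild-type and 0.115% in knockout-labelled libraries, and below 100 CPM 28 and 1 genes did.

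Y-linked genes were present in all 17 libraries: Ddx3y ran from 190.6 to 260.8 CPM, Eif2s3y from 422.8 to 497.7 CPM and Uty from 82.97 to 102.9 CPM. Xist was at 15.1 CPM ± 2.86 in libraries labelled knockout (SD, n = 9) and 9.49 ± 2.42 in wild type (n = 8), with an edgeR adjusted p of 5.03e-06. Kdm5d was at 94.5 CPM ± 5.15 and 80.2 ± 3.43 (adjusted p = 6.40e-06).

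Other splits of the mice were counted with the real one included. For genotype, 1 of 100 splits in sedentary mice, 1 of 35 in running mice and 1 of 100 averaged gave as many genes past the threshold, and the highest other splits gave 1349, 7 and 1544 genes. The splits with 1349 and 1544 genes exchanged the labels of nearly all libraries, so they still kept the genotypes largely apart. In running mice a split and its mirror image were counted as the same split. For genes at an unadjusted p under 0.05, 13 of 35 splits gave as many for running in wild type and 75 of 100 in knockout-labelled mice. It was 54 of 100 for the difference in the running effect and 41 of 100 for running averaged, and 64 of 100 regroupings gave a correlation of the running effects as far from 0.

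Libraries of the same genotype differed by little more than counting noise except in the most abundant genes. Totals that differed 7.9-fold argue against values rescaled to a common depth. Nuclei or amplified cDNA shared between libraries of a genotype cannot be told apart from mice alike in their newborn neurons. At 1 to 2 CPM the squared spread beyond counting was 20.1 times as large between genotypes as between libraries of a genotype, but any difference between genotypes raises this ratio. Read as draws of molecules, the spread at that level within a genotype corresponds to 5.77e+07 molecules per wild-type and 1.39e+08 per knockout-labelled library. At 2 SE more spread it was 3.38e+07 and 5.00e+07, from 200 to 500 nuclei per mouse. The squared spread beyond counting was 0.0120 in wild-type and 0.0050 in knockout-labelled libraries there, but 0.0035 and 0.0085 at 2 to 4 CPM. The order of the genotypes turned, so the implied numbers are rough. Without sharing, the 200 to 500 nuclei of each mouse would have had to yield molecules in these numbers. Read the same way, the spread between genotypes corresponds to fewer molecules per genotype than any of these numbers per library. A draw shared within a genotype would give that order, but a difference between genotypes would also lower the number per genotype. Molecules per nucleus were not measured, so whether nuclei yield enough was not tested, and neither explanation is excluded. Both allow the median pair index of 1.08, and no label names a pool. If libraries shared material, the genotype p-values rest on fewer independent units than 17, down to 1 per genotype. If material was shared across housing, a difference between running and sedentary mice could have been masked.

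Many genes differed between libraries labelled knockout and wild type. Up to 32 CPM the squared spread between genotypes fell with the level at a slope of -0.85 (SE 0.0188) on log scales, nearer to the -1 of few molecules drawn a single time per genotype than to 0, though apart from -1 by more than its error, which is a candidate explanation for weakly expressed genes such as Zbtb9 and Nox4. In the 3 bins with mean levels from 175.1 to 666.4 CPM the slope was -0.22 (SE 0.082), which argues against it for genes of that range, such as Cdr1. GC content and gene length took up 2.33% of the variance of called fold changes (5.87% for called genes above 16 CPM), which argues against them as the whole source. With the runs of identifiers as a term 5303 genes passed, and genotype calls remained within the middle run alone. This argues against differences between the runs as the whole source. Inside the middle run the identifiers came in blocks of the same genotype, with wild type at both ends and knockout-labelled mice between. Wild-type pairs from opposite ends had a pair index of at most 1.335 without Malat1, against at least 1.80 between genotypes. This argues against a steady drift with their order as the whole source. An effect of the blocks themselves cannot be told apart from genotype. A genotype effect stays open and was not tested apart from anything else that was shared within a genotype.

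Fndc5 was not lower in libraries labelled knockout, and its lowest level in any library was 21.1 CPM. 0 annotated genes overlap its exons, which argues against reads of an overlapping gene. 0 libraries lay closer to the other genotype, which argues against single libraries swapped between the genotypes. Reads from exons outside the deleted part cannot be told apart from reads of an intact gene, since the difference of 0.34 in log2(CPM + 1) rests on counts of the whole gene. Counts per exon would be needed to test it.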
